A study of Arabidopsis thaliana with 4 samples.

How the data were processed

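The series holds 4 Arabidopsis thaliana samples, each hybridised as biotin-labelled RNA to 1 Affymetrix ATH1 array. Plants of wild type (Col-0) or of sfr6, a mutant made by chemical mutagenesis in the Col-0 background, were raised on agar for 7 days and then moved to a bright cabinet (240 microEinsteins, 16 h of light and 8 h of dark per day) for 24 h. They then stayed in the light or were kept dark under foil for 3 h, per the labels. The labels give the tissue as cell culture, while the treatment text describes plants on agar plates, and the text here follows the treatment text. Each of the 4 groups (wild type in light, wild type in dark, sfr6 in light, sfr6 in dark) has 1 array, so no group has a replicate.

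The deposited values are MAS5 intensity values on a linear scale, per the submitters' processing notes, which name MAS5 and no version. The mean over all probe sets with the lowest and highest 2% left out was 100 on each of the 4 arrays, so the arrays had been scaled to 1 level. No detection calls were used here. The table has 22810 probe sets, of which 64 are controls and were left out of every comparison between groups.

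Gene names came from the platform annotation given with the series, updated through a RefSeq gene table (assembly TAIR10.1, used for names alone). It gave 1 gene for 13513 probe sets, several for 503 and none for 8730, and 13436 of the first were found in the RefSeq table. No gene was named from a probe set with several genes. Measured and named probe sets covered 8100 genes. Many well-known genes have no named probe set here, among them SFR6 itself (MED16, a subunit of the Mediator complex that links transcription factors to RNA polymerase II), which is not analysed here.

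From the deposited intensity values, any signal under the floor was set to the floor, the 40th percentile of all signals (22.1), and log2 was taken. A probe set entered a comparison when it was at or over the floor on at least 1 of its arrays. Of 22746 probe sets, 15121 were over the floor on at least 1 array and 12147 on all 4. Where the dimmer side lay under the floor, a fold is a lower bound and is written as at least that many fold. Average log2 effects and their SEs were fitted to floored signals, so those of such genes depend on the floor. The average bounds the size from below where both of its differences have the same direction and the floor only shrinks them. The SE is not a bound. The number over the floor was 13968 (61.4%) for wild type in light, 13229 (58.2%) for wild type in dark, 14006 (61.6%) for sfr6 in light and 13387 (58.9%) for sfr6 in dark. The number of arrays limits the precision of every value.

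Pairwise differences and the difference of the dark response between genotypes are values with no test, counted as higher or lower from 2-fold. The average dark effect and the average genotype effect were tested with limma 3.58.1 in R 4.3.3 (additive model of genotype and darkness, lmFit and eBayes with an intensity trend, Benjamini-Hochberg adjusted p under 0.05 over 15121 probe sets). That model has 1 residual degree of freedom, taken from the difference between the genotypes' dark responses, so it treats the genotypes as blocks and assumes that both effects add. The trend prior held 5.15 degrees of freedom. "Rose" and "fell" are used for the average dark effect past that threshold. Figures were drawn with matplotlib 3.10.9.

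The fit was tested on simulated data for the average dark effect over 15121 probe sets, with 200 changed. With variances drawn from the fitted prior, 74 of 100 changes of 1 on the log2 scale and 100 of 100 changes of 2 were recovered, and 20 of 194 calls were false. With each probe set's own fitted variance, 100 of 100 were recovered at either size, but 59 of 259 calls were false and 17 probe sets were called for a genotype effect that was not there. The prior-based simulation was added after the other had been seen. In both, the false share was above the nominal 5%, and the prior-based simulation gave 0 genotype calls. A far smaller share of probe sets was changed than the 33.1% called for darkness in the data. The false share therefore need not carry over to those calls.

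Before the data were examined, 25 gene lists with 356 distinct genes, the rule for named genes, the tests and all alternatives except 2 were fixed. Of those genes 56 were measured under a name, and 9 lists had at least 3 such genes. The lists for shade response, CBF transcription factors, abscisic acid, salicylic acid, jasmonate and ethylene, nitrogen assimilation, cell division and seed storage had none and are not analysed here. A further 12 family lists were chosen after it was known which probe sets carry names, but before any difference was computed; 10 had at least 3 measured genes, and a cytokinin list had none. A gene with several probe sets was represented by the brightest. A list's median difference was set against 10000 random lists of the same size matched on mean signal in 20 bins, and its percentile describes these arrays only. Across 5 differences, 95 list comparisons were made. Calls adjusted over a list alone correct for the genes of that list and not for the number of lists. For genotype, 2989 of 15121 probe sets had an unadjusted limma p under 0.05, so such calls in short lists are weak support.

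Named genes were taken by rule. For darkness, these were the 12 genes highest and the 12 lowest by the smaller of the genotypes' differences, among those at least 2-fold in both genotypes that passed limma's test. For genotype the same rule was applied to light and dark; fewer than 12 passed in the higher direction, so the 10 that were 2-fold in both were used. For the difference of the dark response, the 10 largest in each direction were used, among probe sets over the floor on at least 2 arrays. Up to 4 members of a list fixed in advance, those with the largest differences, could be named as examples, and every member of the CBF regulon and the clock list. Members of the added family lists, GSTU20 and other genes outside these rules were chosen after their values were seen.

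The alternatives were quantile normalization, centring on the median, a floor at the 20th or 60th percentile, a pseudocount in place of the floor, only probe sets of 1 gene with the plain suffix, the variance model without the trend, an added 2-fold threshold, the mean over a gene's probe sets, and the mean in place of the median of a list. A restriction to probe sets over the floor on all 4 arrays, and a shift of each array by the median log2 offset of 18 spike-in control probe sets, were added after seeing the data. These 18 are the Bio and Cre hybridisation controls, which do not measure how much RNA a sample held. The Dap, Lys, Phe and Thr controls read under the floor on every array and were not used. With no replicates, a count or a median over chosen probe sets was taken as kept within 1.5 times its value, and a list median as kept within 1 SD of its members.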

Results

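The data are expression signals from 4 arrays, 1 each for wild type in light, wild type in dark, sfr6 in light and sfr6 in dark. The series' title names dark-induced expression in sfr6 as its subject. The median signal was 37.9, 34.0, 38.6 and 36.0 in that order. Pearson's r of floored log2 signals across probe sets was 0.97 between genotypes in the light and 0.97 in the dark, against 0.90 between light and dark within either genotype. The control probe set for 25S ribosomal RNA read 122 in wild type and 120 in sfr6 in the light, and 364 in wild type and 1321 in sfr6 in the dark. The ratio of the 3' to the 5' probe set of a first GAPDH control pair was 1.13 for wild type in light, 1.35 for wild type in dark, 1.09 for sfr6 in light and 1.105 for sfr6 in dark. In the other GAPDH pair, the 3' probe set read 2086, 1357, 2414 and 1809 in that order. Its 5' probe set read 2110, 1431, 2741 and 1863. Over 18 spike-in control probe sets, the median log2 difference of sfr6 from wild type was -0.19 in light and -0.12 in dark, and that of dark from light was -0.04 in wild type and -0.02 in sfr6, with SDs between 0.13 and 0.25.

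The first question is which transcripts respond to 3 h of darkness in both genotypes. Most measured genes of amino acid breakdown and sugar starvation rose, and most of flavonoid synthesis fell. MCCA, a subunit of the methylcrotonyl-CoA carboxylase that degrades leucine, rose 8.73-fold in wild type and 16.2-fold in sfr6. GAT1_2.1, a glutamine amidotransferase-like gene, rose 17.2-fold in wild type and at least 27.9-fold in sfr6. GI, the clock gene GIGANTEA, fell 7.38-fold in wild type and at least 7.25-fold in sfr6.

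By limma, 2325 of 15121 probe sets rose and 2684 fell, 33.1% of those tested. At least 2-fold in the same direction in both genotypes were 681 that rose and 642 that fell, and all of them passed the test. Among named genes, the largest average effect on floored signals was that of AT1G25400, from 24.1 to 1179 in wild type and from 17.8 to 420.5 in sfr6, an average log2 effect of 4.93 ± 0.31 (SE, adjusted p 0.00033), which is a lower bound because the sfr6 light signal lay under the floor. EXLA1, an expansin-like cell wall gene, rose 26.5-fold in wild type and 12.2-fold in sfr6. AT1G02660, which encodes a lipase, rose 17.7-fold and 10.3-fold, and AT5G61590, which encodes the wax-regulating transcription factor DEWAX, rose 7.69-fold and 9.12-fold. AT3G15630, AT3G45730, AT4G37220, AT2G25200, AT1G10020 and AT4G16563 also rose, with average log2 effects between 2.97 and 3.68, lower bounds for AT3G45730 and AT4G16563.

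Among the falls, AT3G44450, which encodes the cryptochrome inhibitor BIC2, went from 512.0 to 28.1 in wild type and from 355.0 to 16.1 in sfr6, an average log2 effect of -4.10 ± 0.15 (adjusted p 0.00014), which bounds the fall from below. AT1G73600, which encodes a phosphoethanolamine methyltransferase of choline synthesis, fell 15.6-fold in wild type and 16.8-fold in sfr6. GH9C2, a cellulase-family gene, fell at least 12.3-fold in wild type and 23.1-fold in sfr6, and the expansin EXPA8 fell at least 15.6-fold and 10.2-fold. GT72B1, a glycosyltransferase gene, fell 12.1-fold and 13.5-fold. AT2G27420, AT1G60590, AT5G42760, AT1G57590, AT3G48460 and AT1G65870 fell with average log2 effects between -2.81 and -3.96 on floored signals. A dark signal of AT2G27420, AT1G60590, AT1G57590 and AT1G65870 lay under the floor, so theirs bound the fall from below.

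**Figure D1:**
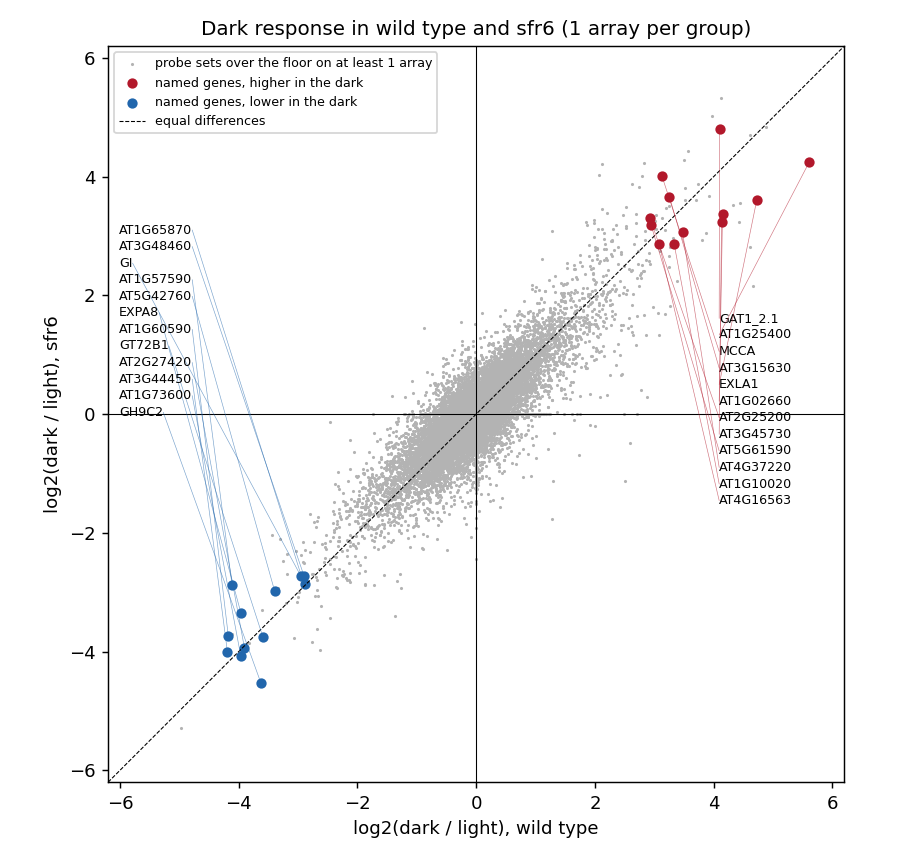
Log2 ratio of dark to light for each probe set in wild type (x axis) and sfr6 (y axis), 1 array per group; grey points are the 15121 probe sets over the floor on at least 1 array and coloured points are the named genes. Of the named genes, GAT1_2.1 is highest on the sfr6 axis, AT1G25400 lies farthest to the right and GH9C2 is lowest.

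Of 3 measured genes of the dark- and sugar-starvation list, 3 rose, also when adjusted over the list alone. AKINBETA1, a subunit of the SnRK1 energy-sensing kinase, rose 5.75-fold in wild type and 8.98-fold in sfr6. ATL8, a RING-type ubiquitin ligase gene, rose 7.22-fold and 6.07-fold, and AT3G15450 (SEN5) rose 1.92-fold and 4.53-fold. The list's median log2 difference was 2.52 in wild type and 2.60 in sfr6, at percentiles 99.995 and 99.975 of random lists. The list of branched-chain amino acid and proline breakdown had 9 measured genes, without its proline gene PRODH1. Of these 9 genes, 6 rose, and 6 when adjusted over the list alone, with a median of 1.93 in wild type and 2.07 in sfr6 (percentile 100 in both). Besides MCCA, those with the largest effects were AT4G33150, which degrades lysine, MCCB and IVD, with average log2 effects of 2.53, 2.32 and 2.29. Of 7 measured autophagy genes, all of the ATG8 family, 4 rose, and 6 when adjusted over the list alone. ATG8E rose 5.39-fold in wild type and 4.74-fold in sfr6, and the list's medians were 0.49 and 0.54 at percentiles 97.05 and 97.23.

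Of 4 measured flavonoid genes, 3 fell, and 3 when adjusted over the list alone. They were UGT78D1, UGT78D2 and CHIL, with average log2 effects of -1.73, -1.21 and -1.48, and the list's median was -1.34 in wild type and -1.35 in sfr6 (percentiles 0.06 and 0.05). DFR did not pass: its signal was 60.9 in light and 84.2 in dark in wild type, and 213.7 and 110.3 in sfr6. Of 3 measured starch genes, PWD and APL3 fell, and 3 fell when adjusted over the list alone; the medians were -0.72 and -0.56 at percentiles 4.64 and 8.55. HYH, a light-signalling bZIP factor, fell with an average log2 effect of -1.24, and PORB, which makes chlorophyllide, rose by 1.46, while CHLM, the other measured chlorophyll gene, did not pass, at 0.11.

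Few of the measured nuclear photosynthesis genes passed the test. Of 3 measured antenna genes, all of them LHCB4 genes, LHCB4.3 fell by 0.41 on the log2 scale, and 1 fell when adjusted over the list alone. The other antenna genes of the list were not measured. Of 7 measured genes of the photosystems and the Calvin cycle, 0 passed, with a median of -0.18 in wild type and -0.12 in sfr6. Of 3 measured Mediator subunit genes, MED6 rose by 0.81 on the log2 scale, and the list's median was 0.10 in wild type and 0.13 in sfr6. The ribosomal protein gene AT2G19730 fell, with a log2 effect of -0.40, and AT3G09630 did not pass, at -0.16. The root marker PYK10 fell, from 3004 to 2081 in wild type and from 2562 to 1823 in sfr6, and the root-hair gene EXPA7 did not pass, at -0.61 ± 0.21; 2 fell when adjusted over the list alone. The 25S ribosomal RNA signal was higher on both dark arrays, beside all of these groups. The test rests on 1 residual degree of freedom, and its false share in simulated data with 200 changed probe sets was above the nominal 5%.

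**Figure D2:**
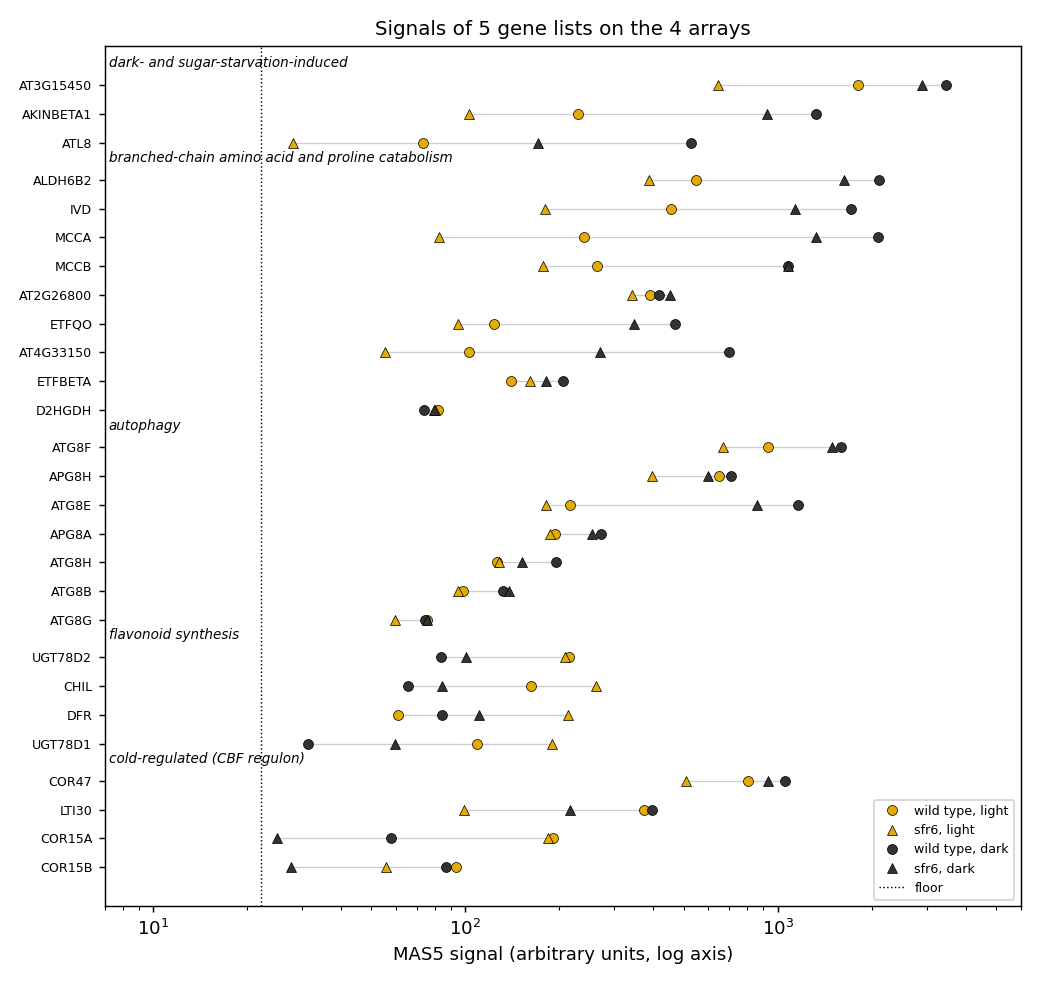
MAS5 signal on a log axis for each measured gene of 5 lists, with circles for wild type, triangles for sfr6, yellow for light and dark grey for darkness, 1 array each; the dotted line is the floor of 22.1. ATL8 and MCCA are lowest in sfr6 in light and highest in wild type in dark, and COR15A is lowest in sfr6 in dark.

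The second question is whether the dark response differs between the genotypes, taken first for each genotype alone. The medians of the starvation and amino acid breakdown lists were higher in the dark in wild type and in sfr6, and that of the flavonoid list lower, by the values above. In wild type, 939 of 14513 probe sets were at least 2-fold higher in dark and 1043 lower. In sfr6, 998 of 14564 were higher and 1001 lower. Among 13956 probe sets that entered both comparisons, 681 of the 922 that were higher in wild type were also higher in sfr6 (65.9 expected for independent lists), and 642 of 1036 that were lower (73.0 expected). In the opposite direction by 2-fold were 3 and 0. Pearson's r of the responses across these probe sets was 0.86 and Spearman's rho 0.80, with no array shared; genes are not independent replicates.

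The response was of similar size in both genotypes. Probe sets chosen as 2-fold higher in wild type had a median log2 response of 1.44 there and 1.33 in sfr6, and those chosen in sfr6 had 1.39 there and 1.26 in wild type. Those chosen as lower in wild type had -1.36 there and -1.16 in sfr6, and those chosen in sfr6 had -1.33 there and -1.26 in wild type. The SD of the response across 15121 probe sets was 0.73 in both genotypes. The pairwise values have no replicate check.

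The response in sfr6 relative to wild type was lowest, among named genes, for AT4G34950, a gene of the major facilitator family, which was 2.42-fold higher in dark in wild type and 3.39-fold lower in sfr6. AT5G18840, a sugar transporter-like gene, went from 35.4 to 230.0 in wild type and from 22.04 to 20.8 in sfr6. AT2G41090, a calmodulin-like gene, was 3.32-fold higher in wild type and 1.60-fold lower in sfr6, and XTH18, a xyloglucan-modifying enzyme, was 3.75-fold higher and 1.13-fold lower. AT5G48570, which encodes the heat-inducible chaperone FKBP65, was 2.44-fold higher in wild type and at least 2.18-fold lower in sfr6. AT1G10340 went from 15.7 to 162.5 in wild type and from 6.7 to 27.0 in sfr6. AT1G47400, which encodes an iron-deficiency signalling peptide, was at 57.1 in light and 10.2 in dark in wild type, and at 312.9 and 29.5 in sfr6. AT2G16660, AT3G28220 and AT4G35940 had response differences of -1.98, -1.97 and -1.86.

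Of the touch and early stress list, CML38 went from 7.6 to 124.6 in wild type and from 2.1 to 10.9 in sfr6, while STZ, a zinc-finger stress regulator, rose in the average test, with a log2 effect of 0.70 ± 0.20, a lower bound. The heat shock gene AT1G53540 was over the floor in wild type in dark alone, at 35.4, and ATHSP22.0 in sfr6 in light alone, at 25.5. PYE, a regulator of iron-deficiency genes, was at 47.6 and 56.1 in wild type and at 76.2 and 27.7 in sfr6. The 3' to 5' ratio of the first GAPDH pair was highest on the wild-type dark array, at 1.35, but that of the other GAPDH pair was not.

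The starvation list's median response difference was 0.64 (percentile 99.72), from 3 genes that disagreed: 1.24 for AT3G15450, 0.64 for AKINBETA1 and -0.25 for ATL8. The median was 0.14 for amino acid breakdown, 0.12 for autophagy, -0.11 for flavonoid genes and -0.22 for the CBF regulon (percentiles 81.8, 72.2, 20.5 and 5.41). Among single genes, the chloroplast transcript rps14 was 1.84-fold lower in dark in wild type and at least 2.72-fold higher in sfr6. The chloroplast transcripts petG and ndhF had response differences of 1.45 and 1.54. Most chloroplast transcripts went the other way: 26 of 43 of photosynthesis and 15 of 21 of gene expression were below 0, with medians of -0.13 and -0.19. TBL45 was 2.16-fold higher in dark in wild type and 6.08-fold higher in sfr6, and AT3G12710 was 1.08-fold and 3.26-fold higher. AT1G78995, AT1G32780, AT4G35510, AT3G53100 and AT3G18800 had response differences between 1.46 and 1.73. In all, 163 of 15121 probe sets had a response at least 2-fold higher in sfr6 and 224 one at least 2-fold lower, against 112 and 289 when the arrays were centred on the spike-in controls. The interaction has no residual degree of freedom, so none of these differences was tested. Some signals of rps14, ndhF, AT1G32780, AT5G18840, AT1G10340, AT5G48570, AT1G47400 and AT4G35940 lay under the floor, so their response differences depend on it. For rps14, AT5G18840 and AT4G35940 these signals were close to the floor. The differences of AT1G10340 and AT1G47400, -2.59 and -2.04 on floored signals, are smaller in size on the signals as printed. That of AT1G32780, 1.68 on floored signals, is smaller too, at 96.4 in light and 18.5 in dark in wild type and 30.0 and 11.3 in sfr6. Without the floor, AT1G47400 and AT1G32780 lie under 2-fold.

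The remaining question is what differs between sfr6 and wild type within a light condition. AT5G64120, a peroxidase gene, was 5.57-fold lower in sfr6 in light and 4.96-fold lower in dark. The medians of starvation and of amino acid breakdown genes were lower in sfr6 in both conditions, and lowest in light. Of 4 measured genes of the cold-regulated CBF regulon 0 passed over all genes, and the list's median log2 difference was -0.70 in light and -1.04 in dark. GSTU22 and GSTU25, glutathione transferase genes, passed as higher in sfr6, GSTU22 by 2.35-fold in light and 3.52-fold in dark.

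In light, 148 of 14658 probe sets were at least 2-fold higher in sfr6 and 252 lower; in dark, 108 of 13930 were higher and 233 lower. At least 2-fold in both conditions were 25 higher and 70 lower, against 0.97 and 3.74 expected for independent lists, and Pearson's r between the conditions was 0.53 across 13467 probe sets, with no array shared. By limma, 63 of 15121 probe sets were higher in sfr6 and 130 lower (1708 and 1281 at an unadjusted p under 0.05, together 2989 where chance gives 756, so the larger share was then higher). With quantile normalization these counts were 21 and 82, and with median centring 6 and 26. They were 0 and 2 without the intensity trend and 278 and 340 over probe sets above the floor on all 4 arrays, so the count of genotype calls depends on the setting. Centring on the spike-in controls, chosen after seeing the data, moved the median of all probe sets by 0.21 in light and 0.13 in dark and gave 963 higher and 201 lower by limma, 373 and 141 from 2-fold in light and 201 and 173 in dark. Which direction holds more genotype calls therefore depends on the scale, and the differences given here are on the deposited one.

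Named genes lower in sfr6 were led by AT1G67865, at 152.7 in wild type and 21.2 in sfr6 in light and at 188.4 and 27.3 in dark, with an average log2 effect of -2.79 ± 0.17 and an adjusted p of 0.0083, which bounds the difference from below. AT3G49160, a pyruvate kinase-family gene, was at least 4.196-fold lower in light and 3.40-fold lower in dark, and AT4G15680, a glutaredoxin gene, 4.31-fold and 3.21-fold lower. AT1G66100, a thionin gene, was 2.87-fold and 4.03-fold lower. AT1G19530, which rose in the dark, was 5.35-fold lower in light and 3.35-fold lower in dark. AT1G09500, AT5G33370, AT4G39675, AT3G45160, AT1G69890 and ATL8 passed with average log2 effects between -1.501 and -1.80, bounds for AT5G33370 and AT1G69890.

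Named genes higher in sfr6 were AT5G01870, a lipid transfer protein gene, at 2.46-fold in light and 2.60-fold in dark (average log2 effect 1.34 ± 0.11, adjusted p 0.013), and SUFE2, an activator of iron-sulphur cluster assembly, at least 2.74-fold and 2.42-fold. AT3G01190, a peroxidase gene, was 2.06-fold and 2.60-fold higher. GSTU25, AT5G48360, AT3G22620, AT2G22510 and the glycosyltransferase gene UGT73B4 also passed, with average log2 effects from 1.097 to 1.34, lower bounds for AT5G48360 and UGT73B4. AT5G05250 was 2.04-fold higher in light and at least 2.13-fold higher in dark, with an adjusted p of 0.053.

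**Figure D3:**
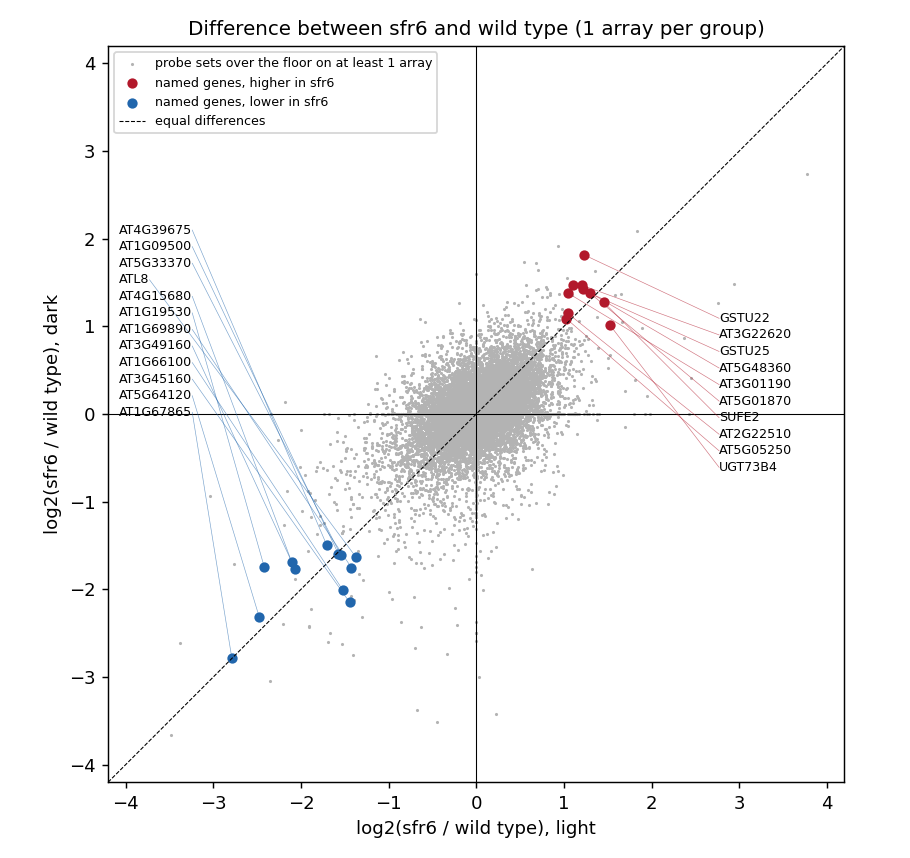
Log2 ratio of sfr6 to wild type for each probe set in light (x axis) and dark (y axis), 1 array per group; grey points are probe sets over the floor on at least 1 array, coloured points are the named genes, and the dashed line marks equal differences. AT1G67865 and AT5G64120 lie farthest from 0 among the genes named for this comparison, and the lower group spreads wider than the higher one.

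Of 4 measured CBF-regulon genes, which are induced by cold through the CBF factors, 0 passed for genotype in the test over all genes and 3 were lower when adjusted over the list alone. LTI30, a dehydrin gene, was 3.78-fold lower in sfr6 in light and 1.83-fold lower in dark. COR15B was 1.68-fold and 3.155-fold lower, COR15A 1.04-fold and 2.32-fold lower, and COR47 1.58-fold and 1.13-fold lower. The list's median log2 difference was -0.70 in light and -1.04 in dark, at percentiles 0.09 and 0.00 of random lists, and the latter was -0.38 with the floor at the 60th percentile. In the average dark effect COR47 rose, at 0.63, and COR15A fell, at -2.30, and the list's median dark response was -0.01 in wild type and -0.07 in sfr6, against 0.05 in wild type when centred on the spike-in controls and 0.44 in sfr6 with the floor at the 60th percentile.

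Of 3 starvation genes, ATL8 passed for genotype, and 3 were lower when adjusted over the list alone; the list's median was -1.38 in light and -0.52 in dark (percentiles 0.01 and 1.01). Of 9 amino acid breakdown genes, AT4G33150 passed and 5 were lower when adjusted over the list alone, with a median of -0.50 in light and -0.37 in dark (percentiles 0.07 and 0.05). MCCA was 2.91-fold lower in light and 1.57-fold lower in dark, and IVD 2.54-fold and 1.505-fold lower. Of 4 flavonoid genes, 0 passed and 3 were higher when adjusted over the list alone, with a median of 0.75 in light and 0.37 in dark (percentiles 99.99 and 97.4). DFR was 3.51-fold higher in sfr6 in light and 1.31-fold higher in dark. Autophagy, starch, Mediator, photosystem and antenna lists had 0 genes past the test over all genes, with medians from -0.37 to 0.06 in light and from -0.28 to 0.00 in dark. Adjusted over the list alone, 3 antenna genes were lower in sfr6 and 0 of the other 4 lists passed; the photosystem median in dark was -0.14, and 0.034 with quantile normalization. Centred on the spike-in controls, the photosystem medians were about 0, the starch median in light was 0.21 and the autophagy median in dark 0.05, against -0.01 and -0.09 on the deposited scale.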

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

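The tests on touch and heat genes, on chloroplast transcripts and on probe sets split by mean signal were chosen after related values had been seen, the last in place of a split by the highest signal, which the change itself decides.

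Of 119 genes compared, 37 had effects of opposite sign: 20 in the dark responses of the genotypes and 29 in the differences of sfr6 from wild type in light and dark, with 12 in both. These differences were not tested, because each group has 1 array, and genes named for a large response difference are more prone to be among them. The log2 difference of the dark response, sfr6 minus wild type, was -3.03 for AT4G34950, -2.41 for AT2G41090, -2.41 for AT5G48570, -2.09 for XTH18, -1.98 for AT2G16660, -1.97 for AT3G28220, -1.86 for AT4G35940, -1.70 for PYE, -1.42 for DFR and -1.12 for EXLA1. It was 2.32 for rps14, 1.73 for AT1G78995, 1.60 for AT3G12710, 1.54 for ndhF, 1.497 for AT4G35510, 1.495 for TBL45, 1.49 for AT3G53100, 1.46 for AT3G18800, 1.45 for petG and 1.23 for AT1G57590. The other 17 were under 2-fold: -0.47 for AT1G10020, -0.39 for ETFBETA, -0.39 for ATG8H, -0.36 for MED6, -0.18 for SUFE2, 0.61 for EXPA8, 0.38 for SBPASE, 0.36 for DPE1, 0.36 for ATG8G, 0.32 for UGT78D2, 0.31 for AT2G26800, 0.22 for AT1G65870, 0.19 for LHCB4.2, 0.16 for AT5G64120, 0.16 for CHLM, 0.14 for D2HGDH and 0.12 for ATG8B.

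Many of the genes with a lower response in sfr6, such as CML38, XTH18 and AT2G41090, were high on the wild-type dark array alone. Among probe sets with a geometric mean signal of 100 or more, 53 were at least 2-fold above the other 3 arrays on the wild-type dark array. Against 14 on the sfr6 light array this is a ratio of 3.79. Dim probe sets were left out here by the choice of signal, so this ratio does not test noise of dim probe sets. Under 100 there were 67 and 69, a ratio of 0.97, so such noise stays open for dim genes such as CML38 and XTH18. These counts do not require a lower response in sfr6. ATL8, which rose in the dark and was lower in sfr6 in both conditions, qualified with a response difference of -0.25. The 53 therefore do not measure how many genes had a lower response in sfr6. Of those with a mean of 100 or more, 91 were at least 2-fold below the other 3 arrays on the sfr6 light array and 32 on the wild-type dark array. Genes that rose in the dark and were lower in sfr6 in both conditions can be lowest on the sfr6 light array without a 2-fold response difference. ATL8 and AT1G19530 were, with response differences of -0.25 and 0.68. The 91 thus do not show that the sfr6 light array stands apart. Handling or warming of the wild-type dark plate may also raise genes on its array alone. The 4 measured touch and heat shock genes, with a median response difference of -0.64, are too few to decide. With 1 array per group, an effect of the wild-type dark plate or array and a need for SFR6 in the dark cannot be told apart. The 3' to 5' ratios of the first GAPDH pair, 1.35, of ubiquitin, 1.44, and of an actin pair, 1.765, were highest on this array. The other GAPDH pair did not follow. In wild type its dark minus light log2 difference was -0.62 for the 3' and -0.56 for the 5' probe set. The ratio of the 3' to the middle probe set of actin was 1.51 on the wild-type light array and 1.49 on this one. The controls thus disagree, and RNA quality stays open as well.

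The control probe set for 25S ribosomal RNA, which no comparison uses, gave a signal in darkness 3.00 times that in light in wild type and 11.03 times in sfr6. The 5S control did not follow: it was at 77.6 and 45.9 in light and dark in wild type and at 28.2 and 18.1 in sfr6. If RNA without poly(A) tails had been carried over in general, the 64 chloroplast-encoded transcripts would be expected to be higher in sfr6 in the dark too, but their median log2 difference from wild type there was -0.13, with an SD of 0.35 over genes, which argues against it. A change in ribosomal RNA itself in the dark remains open and was not tested.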

How the results depend on the processing

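The restriction to probe sets over the floor on all 4 arrays and centring on the spike-in controls were chosen after seeing the data. No paired analysis was possible because each group has 1 array and the labels give the same replicate number to all 4, so no replicate number pairs the arrays; the additive model pairs light and dark by genotype alone. Of the counts, correlations and medians over chosen probe sets, 96 values under the alternatives were within 1.5 times and 64 moved further. Of 940 list medians under the alternatives, 927 moved by no more than 1 SD of the members, and 51, from 26 medians, had the other sign, 12 of them when centred on the spike-in controls. They include the CBF regulon's response difference, -0.22, which was 0.29 with the floor at the 60th percentile. Of the named genes' differences 804 stayed on their side of 2-fold, 44 were under it and 0 turned; 4 of these were exactly 0 with the floor at the 60th percentile, SUFE2, AT5G05250 and UGT73B4 for genotype in dark and ndhF for the response, and were counted so after they had been seen. The counts of probe sets higher in dark moved by over 1.5 times only where fewer probe sets were tested or a 2-fold threshold was added. Signal over background limits the counts, since the floor decides how many dim probe sets enter. Unless stated, the cause of a move was not tested.

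With the floor at the 20th percentile, probe sets lower in dark were 1807 in wild type and 1665 in sfr6, those higher and lower in sfr6 were 438 and 552 in light and 398 and 459 in dark, the response was higher for 626 and lower for 711, genotype calls were 251 and 344, and the starch median in wild type was -0.89. With the floor at the 60th percentile, those lower in dark were 568 and 523, those higher and lower in sfr6 63 and 160 in light and 39 and 151 in dark, the response was higher for 64 and lower for 115, and 1727 fell in the average dark effect. There, limma called 0 higher and 3 lower for genotype (1157 and 922 at an unadjusted p under 0.05), and the median of sfr6 minus wild type was -1.16 for starvation genes in light and -0.38 for the CBF regulon in dark.

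With a pseudocount in place of the floor, those lower in dark were 684 and 606, those higher and lower in sfr6 55 and 156 in light and 38 and 155 in dark, the response was higher for 59 and lower for 106, genotype calls were 2 and 10, and the starvation median in light was -1.02. With only plain probe sets of 1 gene, where fewer are tested by construction, counts in dark were 499 and 496 in wild type and 547 and 473 in sfr6, those higher and lower in sfr6 65 and 118 in light and 55 and 111 in dark, the response 97 and 107, and the average dark effect 1285 and 1360. Quantile normalization gave 21 and 82 genotype calls, 70 higher in sfr6 in dark, and photosystem medians of -0.040 for darkness in sfr6 and 0.034 for sfr6 minus wild type in dark. Median centring gave 6 and 26 genotype calls. Centring on the spike-in controls gave 963 and 201, with 373 higher and 141 lower in sfr6 in light and 201 higher in dark, a starvation median in light of -1.15, photosystem medians for sfr6 minus wild type of 0.0014 in light and 0.00020 in dark, and a Mediator median in light of 0.29; here the shift of every signal on an array is the cause by construction. Without the intensity trend, limma called 0 and 2 for genotype (1606 and 1111 at an unadjusted p under 0.05). With a 2-fold threshold added in both genotypes or both conditions, dark calls were 681 and 642 and genotype calls 22 and 67.

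With only probe sets over the floor on all 4 arrays, 74 were higher in sfr6 in light, 152 lower in sfr6 in dark, 124 had a lower response, and genotype calls were 278 and 340. The early auxin median was then 0.88 for darkness in sfr6 and 0.28 for sfr6 minus wild type in dark, turned from -0.24, and the U-box ligase median was -0.36 for sfr6 minus wild type in light; fewer members were measured.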

Other observations

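The tests of array scaling, with the spike-in controls among the scales, were chosen after related values had been seen, in place of a test on amino acid breakdown genes alone that had argued against scaling. The rule for the absolute level was also changed when the spike-in scale was added: it had counted for scaling a value above -0.05 on either of the other scales, and taken over any scale it would count the spike-in value for scaling, while it now asks for all 3 and leaves this undecided. The family lists in the first paragraphs were chosen after it was known which probe sets carry names, with their named members chosen after the values were seen.

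Of 10 measured glutathione transferase genes, 7 fell and 0 rose, with a median log2 difference of -0.68 in wild type and -0.63 in sfr6 (percentiles 0.01 and 0.06 of random lists), and 3 of them, GSTU20, GSTU22 and GSTU25, were also higher in sfr6 by limma. Of 32 UDP-glycosyltransferase genes, 15 fell and 5 rose, with medians of -0.34 and -0.29. UGT73C1 fell with an average log2 effect of -2.22, and UGT71C2 rose with 1.88. Of 20 expansin and xyloglucan enzyme genes, 9 fell and 3 rose: EXPB3 fell with -2.86 and EXPA15 with -2.46, while EXLA1 rose with 4.17. Of 18 subtilase and serine carboxypeptidase-like genes, 8 fell and SCPL34 rose. For genotype 0 of these 18 passed, over all genes or adjusted over the list alone, and the list's median for sfr6 minus wild type was 0.20 in light and 0.37 in dark (percentiles 96.8 and 100). Of 7 SWEET sugar transporter genes, SWEET13, SWEET17 and SWEET11 fell and SWEET2 rose, by 1.04 on the log2 scale. SWEET2 was also lower in sfr6, at -0.83, and the family's median for sfr6 minus wild type was -0.39 in light and -0.51 in dark, at percentiles 1.38 and 0.08.

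Of 7 tubulin genes, TUA6, TUB7 and TUB1 fell in the dark. For genotype 0 passed over all genes and 6 were higher in sfr6 when adjusted over the list alone, with a median of 0.45 in light and 0.35 in dark (percentiles 99.76 and 98.98). Of 43 chloroplast-encoded photosynthesis transcripts 2 rose and 1 fell in the dark, but 0 passed when adjusted over the list alone, and of 21 chloroplast-encoded transcripts of gene expression 3 rose and 1 fell, as they did over the list alone. Their median response differences between sfr6 and wild type were -0.13 and -0.19, at percentiles 0.00 and 0.01. For gene expression, sfr6 was already higher in light, with a median of 0.29 (percentile 99.9, 17 of 21 above 0), against 0.03 in dark, which was -0.03 with median centring; 0 passed for genotype over all genes and 5 were higher when adjusted over the list alone. Of 6 early auxin genes, WES1 and IAA18 rose, with average log2 effects of 1.58 and 0.58. Of 7 U-box ligase genes, PUB19 and PUB26 fell and PUB22 rose. Of 2 measured vacuolar processing genes, BETA-VPE fell.

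Transcripts that rose in the dark lay lower in sfr6, relative to wild type, than those that fell. Of the 2325 probe sets that rose, 70.8% had a lower average in sfr6, with a median genotype effect of -0.13, against 34.0% and 0.13 for the 2684 that fell. Of the 130 probe sets that passed as lower in sfr6, 68 had risen in the dark and 18 had fallen, and of the 63 that passed as higher, 0 had risen and 52 had fallen; centred on the spike-in controls these were 107 and 31 of 201, and 20 and 495 of 963.

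A hypothesis is that sfr6 is shifted against the dark response, and the average dark and genotype effects, whose errors are independent if the arrays are equally noisy, had a Pearson's r of -0.35 across 12147 probe sets over the floor on all 4 arrays. A shift of a whole array by 1 constant cannot separate those that rose from those that fell, and the difference of their medians was -0.26 on the deposited scale and -0.27 under quantile normalization, which argues against scaling that depends on signal. Whether those that rose were lower in sfr6 in absolute terms cannot be told apart from scaling, since their median genotype effect was -0.15 under quantile normalization and -0.18 under median centring, but 0.041 on the spike-in scale. The spike-in scale rests on hybridisation controls, so it is no reference for absolute RNA levels either. Larger noise on the wild-type dark and sfr6 light arrays could make the averages correlate, but it would give no correlation between differences that share only the wild-type light or the sfr6 dark array, where noise of the shared array acts upwards, yet r was -0.15 for the former and -0.19 for the latter. This covers only noise that is independent between arrays. RNA quality stays open, with a 3' to 5' ratio of the first GAPDH pair of 1.35 on the wild-type dark array and 1.09 on the sfr6 light array, though the other GAPDH pair was not highest on the former. A difference in light, time or age between the plates of each genotype stays open too, and neither was tested.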
